A study of Mus musculus with 2 samples.

How the data were processed

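The deposited UMI (unique molecular identifier) counts per gene and cell barcode were used as deposited. The authors had limited the counts to called cells, since no deposited barcode held fewer than 1401 UMIs. Per the submitters' processing notes, Cell Ranger and Seurat were used with the mouse build mm10 (GRCm38), and the notes state no version. Both tables held the same 27998 genes, and the 56 symbols that stood for more than 1 gene were kept apart by their Ensembl identifiers. Gene coordinates were taken from GENCODE vM21 on GRCm38. The analysis ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scanpy 1.11.5, scikit-learn 1.9.0, scikit-image 0.26.0, igraph 0.11.9 and matplotlib 3.10.9.

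The filters, marker genes, gene lists, rule for named genes and most alternative settings were fixed before the data were examined. Cells were kept with at least 500 genes, at least 1000 UMIs and at most 20% mitochondrial UMIs. Doublets were called in each library with Scrublet at an expected rate of 5%. Where its own threshold called under 0.5% or over 15% of a library, the 5% of barcodes with the highest scores were called instead. This happened in the HFD library, where its own threshold called 0 barcodes, and called doublets were left out.

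Both libraries were clustered together without integration, so that no difference between them was removed. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen within libraries, scaled and capped at 10. A graph of 15 neighbours over 30 principal components was clustered by the Leiden method at resolution 1, which gave 25 clusters. Each cluster of at least 40 cells was split once more at resolution 0.3, which gave 74 clusters. This second round and the details of the naming rule were chosen after the first clusters were seen. A cluster was named after the class, of 20 with markers, whose markers had the highest mean log2 fold over the median of the first-round clusters. At least 3 of those markers had to reach 1.5-fold. A cluster with more markers of another class among its 10 leading genes stayed unnamed. The gene table lacked the constant genes of the T cell receptor and Ighm, Ighd and Igha, so the T, B and plasma classes rested on their other markers. Each name therefore means a profile like that class.

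Counts were summed over the cells of each class in each library and given as CPM (counts per 1000000) of that sum. With 1 library per group no test was made. Shares have exact Clopper-Pearson 95% intervals, sums have exact Poisson intervals, and ratios have exact conditional binomial intervals. All of them cover counting error only. A count of 0 was set to 3 for a ratio, which is then a bound. Classes with at least 50 kept cells in each library were compared, and single genes were named in classes with at least 100.

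The 36 gene lists were written from the literature. A list was summarised by the median log2 ratio of HFD CPM over NCD CPM among members with at least 10 CPM in either library. It was placed by percentile among 10000 random lists of the same size and matched on mean CPM in 20 bins. The percentile describes these libraries and is not a p-value. The medians of 11 lists were set as the main ones.

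Named genes had at least 100 CPM in the class in the higher library, a UMI in at least 10% of its cells there, and at least 20% of the level in the highest class. Mitochondrial, ribosomal, haemoglobin, receptor variable, predicted and sex-linked genes were left out. They were ranked by the end of the 95% interval nearest to 1, with up to 10 named each way in the 4 largest classes and up to 4 in the others. Up to 5 members of each described list with at least 50 CPM were named by the size of their log2 ratio, and so were the genes whose shares of cells with a UMI are given. Those shares were taken after every cell was thinned to 2000 UMIs.

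Free RNA, meaning transcripts from other cells caught in a droplet, was estimated after the data were seen. The estimate is the median level of markers of another cell type in a class as a percentage of their level in the whole library. It used 15 stromal markers in immune and endothelial cells and 7 macrophage markers in progenitor and mesothelial cells. The library profile was then subtracted in that proportion. Class values were also recomputed from clusters in which these markers stayed at or below 25% of the library level.

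The code was checked on simulated counts built from the NCD macrophage profile and from the NCD progenitor profile. The 95% intervals held the true ratio for 95.6% of 6751 macrophage genes and 95.5% of 7656 progenitor genes. A 1.5-fold difference was recovered for 91.0% and 96.8% of the genes given it, and 2-fold and 4-fold differences for 100%. With 35% of free RNA added, 35.3% was found, and subtraction lowered the median error from 0.14 to 0.05 log2. The free RNA markers had been taken out of the simulated profiles, and the library profile was added at the same level over the whole class. This checks the code and not whether the data meet these assumptions.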

Results

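The data are single-cell transcriptomes of the stromal vascular fraction of mouse epididymal white adipose tissue, the cells left when adipocytes are removed. Wild-type male C57BL/6J mice of 18 weeks had been fed a normal chow diet (NCD) or, for 12 weeks, a high-fat diet (HFD). Tissue was digested with collagenase II at 1 mg/ml for 30 min at 37 °C. Cells with a viability above 80% were loaded at 6000 per channel of a droplet-based 10x 3' kit and sequenced to at least 50000 reads per cell. There is 1 library per diet, so there are no replicates, and diet and library cannot be separated. The values below describe these 2 libraries.

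The NCD table held 7365 barcodes with 33825656 UMIs, and the HFD table held 6840 barcodes with 18623508 UMIs. The median barcode had 4230 UMIs and 1609 genes in the NCD library, with a range of 1556 to 23161 UMIs. It had 2020 UMIs and 945 genes in the HFD library, with a range of 1401 to 34339 UMIs. After filtering and the removal of 214 NCD and 339 HFD doublets, 7130 NCD cells and 6447 HFD cells were kept. Mitochondrial transcripts made up 2.36% of the UMIs of the median NCD barcode and 3.53% of those of the median HFD barcode.

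The first comparison asked which cell classes made up each library. Macrophages, the main phagocytes of fat tissue, were 28.4% of kept cells in the NCD library (2027 cells, 95% interval 27.4 to 29.5) and 35.5% in the HFD library (2287 cells, 34.3 to 36.7). T cells were 1.94% (138 cells, 1.63 to 2.28) and 3.61% (233 cells, 3.17 to 4.10), B cells 0.898% (64 cells, 0.692 to 1.14) and 2.79% (180 cells, 2.40 to 3.22). Plasma cells were 5.58 times as frequent in the HFD library, with 23 NCD and 116 HFD cells, but the plasma markers Jchain, Mzb1 and Derl3 summed over the whole library were 1.57-fold higher (1.53 to 1.61). In clusters with little free RNA the log2 ratio of their shares was 0.78. That filter left out 97 HFD and 2 NCD plasma cells, so the 0.78 depends on the filter itself. Mast cells or basophils, which store histamine and proteases, were 2 of the NCD cells and 78 of the HFD cells, 0.0281% (0.00340 to 0.101) against 1.21% (0.957 to 1.51). All 78 lay in 1 cluster in which stromal markers stood at 104% and macrophage markers at 50.1% of their library level. Names of classes mean a profile like that class by its marker genes.

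Several classes were less frequent in the HFD library. Type 2 innate lymphoid cells, a source of interleukins 5 and 13, were 1.58% of NCD cells (113 cells, 1.31 to 1.90) and 0.124% of HFD cells (8 cells, 0.0536 to 0.244), 12.8 times lower. Dendritic cells were 5.12% (4.62 to 5.66) and 3.44% (3.01 to 3.92), endothelial cells 4.74% (4.26 to 5.26) and 3.46% (3.03 to 3.93), and monocytes 2.57% (2.21 to 2.96) and 1.35% (1.08 to 1.66). Natural killer cells were 0.912% (65 cells) and 0.372% (24 cells), but 88 NCD and 149 HFD cells when each cell was classed by its own marker score. Mural cells were 32 in the NCD library and 1 in the HFD library, but 310 and 144 by marker score per cell. Adipose stem and progenitor cells, the fibroblast-like cells that give rise to adipocytes, were 44.9% (3200 cells, 43.7 to 46.0) and 45.2% (2917 cells, 44.0 to 46.5). Mesothelial cells were 0.757% and 0.807%, but 0.784% (54 cells) and 0.275% (10 cells) in clusters with little free RNA. That filter left out 42 HFD mesothelial cells and none from the NCD library, so the lower HFD share is not read as a lower frequency.

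Of immune cells alone, macrophages were 68.0% in the NCD library and 70.7% in the HFD library, a log2 ratio of 0.06 with a range of −0.01 to 0.12. This total left out 2 unnamed clusters of 444 NCD and 15 HFD cells, led by the myeloid genes Lyz1 and Retnla. With them counted as immune cells other than macrophages, a setting chosen after seeing the data, the shares were 59.2% and 70.4%. The log2 ratio was then 0.25 (0.18 to 0.32). The marker score of cluster 2.3, with 184 of these NCD and 12 of these HFD cells, was highest for macrophages. Its macrophage markers stood at 160% and 45.4% of their library level, so the 0.25 depends on the naming rule. Of non-immune cells alone, progenitors were 88.3% and 91.4%, and endothelial cells 9.33% and 6.98%. Clusters with no name held 7.38% of NCD cells (6.78 to 8.01) and 0.295% of HFD cells (0.178 to 0.460). The macrophage log2 ratio of 0.32 turned to −0.38 when each cell was classed by its own marker score. Under a stricter cell filter the T cell ratio went from 0.90 to −0.11, the monocyte ratio from −0.93 to 0.03, the dendritic ratio from −0.57 to −1.44 and the mast cell or basophil ratio from 5.43 to 3.12. That filter asked for at least 1000 genes and at most 10% mitochondrial UMIs, and it kept 6311 NCD and 2695 HFD cells. The median kept HFD cell had 945 genes, so most HFD cells were left out and these ratios also depend on depth. The B cell ratio of 1.64 rested partly on a macrophage-rich cluster that held 53.9% of HFD B cells and became 0.44 with no cell filter, and the innate lymphoid ratio of −3.67 became −1.23 by marker score.

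Stromal transcripts were found in immune cells of the HFD library. Decorin (Dcn), a matrix proteoglycan made by fibroblasts, was at 235 CPM in NCD macrophages and 1948 CPM in HFD macrophages. The median of 15 stromal markers in macrophages was 3.25% of the library level in the NCD library and 32.6% in the HFD library. It was 5.98% and 43.4% in T cells, 3.26% and 27.6% in dendritic cells, 2.36% and 38.2% in B cells, and 4.42% and 62.0% in endothelial cells. Macrophage transcripts were likewise found in progenitors, where the median of 7 macrophage markers was 2.78% and 21.8% of the library level, and the complement gene C1qb stood at 43.2 and 452 CPM. In endothelial cells these macrophage markers were at 62.3% and 51.2%. The main values below are therefore also given after subtraction of this free RNA or in clusters with little of it, settings chosen after seeing the data.

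**Figure D1:**
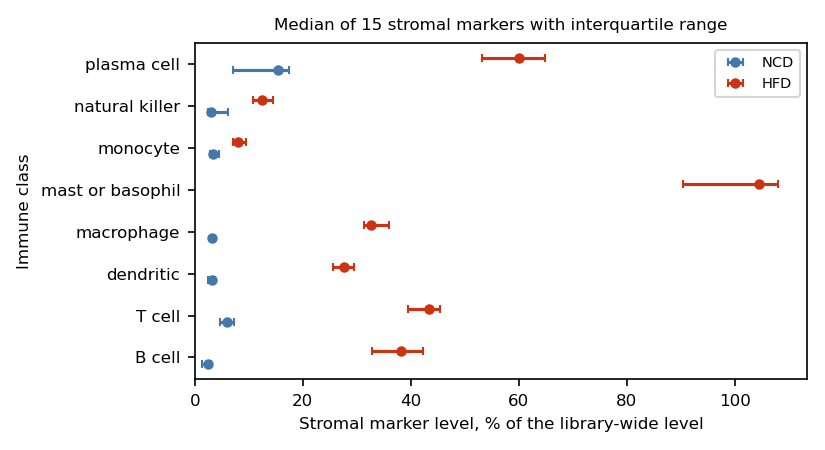
Median level of 15 stromal markers in each immune class, with the interquartile range over the markers, as a percentage of their level in the whole library, for the NCD and HFD libraries. In macrophages the median is 3.25% in the NCD library and 32.6% in the HFD library.

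The second comparison asked which programs of macrophages differed. All 22 measured genes of the lipid-associated macrophage list, which mark phagocytes that take up and break down lipid, were higher in the HFD library. Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), which encodes the secreted adhesion protein osteopontin, was at 2.88 CPM in NCD and 293 CPM in HFD macrophages, 102-fold (67.0 to 163). The elastase gene Mmp12 (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499) was at 13.9 and 917 CPM, 66.1-fold (54.5 to 80.8). Gpnmb (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), which encodes a lysosomal glycoprotein, was at 13.5 and 631 CPM, 46.8-fold (38.5 to 57.5). The tetraspanin gene Cd9 was 21.5-fold higher and the proton pump subunit gene Atp6v0d2 21.2-fold higher. The list median was 2.85 log2, above all 10000 random lists, and 3.08 after subtraction of free RNA.

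All 20 measured resident macrophage genes, which mark the scavenging macrophages of lean tissue, were lower in the HFD library. Retnla (ENSMUSG00000061100, chromosome 16, 48842551 to 48844461), which encodes a resistin-like factor of alternatively activated macrophages, was at 27435 CPM in NCD and 1521 CPM in HFD macrophages, 18.0-fold lower (17.7 to 18.4). The haptoglobin-haemoglobin scavenger receptor gene Cd163 (ENSMUSG00000008845, chromosome 6, 124304656 to 124330527) was at 547 and 32.4 CPM, 16.9-fold lower (14.8 to 19.4). The hyaluronan receptor gene Lyve1 (ENSMUSG00000030787, chromosome 7, 110850607 to 110863239) was at 815 and 55.0 CPM, 14.8-fold lower (13.4 to 16.5). The lectin genes Cd209f and Cd209g were 22.1-fold and 24.9-fold lower. The list median was −2.39 log2, below all 10000 random lists, and −2.20 after subtraction.

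Among the other ranked genes, the collagen-degrading cathepsin gene Ctsk was 62.6-fold higher (5.37 and 336 CPM) and the adhesion gene Cadm1 41.9-fold higher in the HFD library. Mgp, Lum and Pam, which progenitors also transcribe, were higher by 45.5-fold, 36.1-fold and 39.0-fold. In clusters with little free RNA Lum and Pam were higher by 3.87 and 4.36 log2. Those HFD clusters still held stromal markers at up to 24.8% of the library level. Mgp and Lum are among the stromal markers that measured free RNA, so their values are not read as macrophage transcription. The ribonuclease gene Rnase2a (ENSMUSG00000047222, chromosome 14, 51255262 to 51256112) had 1260 UMIs in NCD and 1 UMI in HFD macrophages, 1157-fold lower (207 to 45719). The gelatinase gene Mmp9 was 79.8-fold lower, the phospholipase gene Pla2g2d 77.2-fold lower and the chemokine gene Ccl12 29.6-fold lower. The lectin genes Cd209b, Cd209d and Mgl2 were lower by 26.4-fold, 22.1-fold and 21.3-fold.

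Of 24 lysosome genes, 13 were higher, 2 were lower and 9 had intervals that held 1. The protease genes Ctsd (500.1 and 2839 CPM) and Ctsz were 5.68-fold and 2.46-fold higher, and the list median was 0.17, at percentile 86.5, and 0.32 after subtraction. Of 9 genes of MHC class II, which present antigen to T cells, 7 were lower and 2 higher in the HFD library. H2-Eb1 stood at 6231 and 2602 CPM, H2-Aa at 8536 and 3782 CPM, and the invariant chain gene Cd74 at 26136 and 12478 CPM. The list median was −1.12 log2, at percentile 0.09, and −0.95 after subtraction.

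Other lists also differed in macrophages. Cell cycle genes were higher for 21 of 23 members (median 0.90 log2), with Birc5 at 1.31 and Stmn1 at 1.25. Hypoxia and glycolysis genes were higher for 14 of 20 (median 0.83), with Pkm at 158 and 512 CPM and Aldoa at 218 and 617 CPM. Fatty acid oxidation and PPAR target genes were higher for 13 of 16 (median 0.66), among them the lipid droplet gene Plin2 (535 and 1587 CPM) and Fabp4 (148 and 850 CPM). Iron handling genes were lower for 8 of 14 (median −0.76), and the iron exporter gene Slc40a1 was 10.1-fold lower. Interferon response genes were lower for 15 of 22 (median −0.53), with Ly6e at −2.13. Immediate early genes, which respond to tissue digestion, were lower for 20 of 25 (median −0.55), with Egr1 at −2.18 and Ier3 at −2.15. Among chemokine and cytokine genes, Ccl7 and Ccl2 were lower by 4.07 and 2.67 log2 units, and Cxcl1 and Il1b were higher by 2.62 and 2.29.

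After thinning to 2000 UMIs, which left out 218 NCD and 1031 HFD macrophages, Trem2, a lipid receptor gene, had a UMI in 19.96% of NCD cells (18.1 to 21.9) and 77.0% of HFD cells (74.6 to 79.3). Unthinned, these shares were 30.6% and 75.9%, and in progenitors, as background, 0.264% and 14.1%. Median depth was 3655 and 2104 UMIs in macrophages and 4591 and 1981 UMIs in progenitors. Lyve1 was seen in 60.3% and 5.41% (unthinned 69.9% and 5.99%, background 0.594% and 1.05%). Cd163 was seen in 55.6% and 4.22% (unthinned 66.4% and 5.99%, background 0.528% and 0.560%). Folr2 was seen in 83.7% and 46.7% (unthinned 89.2% and 48.2%, background 2.54% and 8.68%), and Ccr2 in 16.7% and 7.09% (unthinned 22.5% and 10.3%, background 0.760% and 2.45%). Itgax was seen in 0.608% and 7.72% (unthinned 0.888% and 9.75%, background 0.0330% and 1.05%), and Mki67 in 0.940% and 2.47% (unthinned 1.58% and 2.49%, background 0.165% and 0.700%).

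In the HFD library Gpnmb was seen in 39.6% of thinned macrophages (unthinned 40.9%, progenitors 16.7%) and Spp1 in 17.6% (unthinned 18.5%, background 4.83%). The NCD share of Gpnmb was 0.608% (unthinned 0.937%), below the 9.81% of NCD progenitors, which transcribe it. The NCD share of Spp1 was 0.276% (unthinned 0.395%, background 0%), with an interval that overlapped that of the background. Timd4 was seen in 7.19% of NCD macrophages (unthinned 10.6%, background 0.0661%), and its HFD share of 0.637% (unthinned 0.700%, background 0.210%) was read as background. Cd9 (4.92% and 67.3%, unthinned 7.84% and 70.8%) and Lpl (14.0% and 84.5%, unthinned 20.4% and 85.2%) did not have intervals above those of their progenitor shares of 52.3% and 71.7% for Cd9 and 60.5% and 81.3% for Lpl. Progenitors transcribe both genes, so these shares are no background. NCD macrophages lay mainly in cluster 5 (60.2%) and cluster 1 (36.8%), and HFD macrophages in cluster 22 (43.4%) and cluster 20 (40.4%), so no cluster held most macrophages of both libraries.

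The third comparison asked which programs of adipose stem and progenitor cells differed. The stromelysin gene Mmp3 (ENSMUSG00000043613, chromosome 9, 7445822 to 7455975), whose product degrades matrix, was at 15.4 CPM in the NCD library and 282 CPM in the HFD library, 18.3-fold (16.01 to 21.1). The complement gene C4b (ENSMUSG00000073418, chromosome 17, 34728380 to 34743882) was at 31.5 and 348 CPM, 11.1-fold (10.0 to 12.2). The hydrolase gene Abhd2 was 12.7-fold higher, the fibulin gene Fbln7 11.8-fold higher and the metalloproteinase inhibitor gene Timp1 8.81-fold higher (83.4 and 735 CPM). Tmem176a, Tmem176b, Lgmn, Mdk and the zinc transporter gene Slc39a1 were higher by 3.47, 3.11, 3.09, 3.06 and 2.79 log2.

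The sphingomyelinase gene Smpd3 (ENSMUSG00000031906, chromosome 8, 106252548 to 106337988) was at 299 CPM in the NCD library and 22.5 CPM in the HFD library, 13.3-fold lower (11.4 to 15.6). Hsd11b1 (ENSMUSG00000016194, chromosome 1, 193221634 to 193264075), which encodes the enzyme that reactivates glucocorticoids, was at 802 and 71.0 CPM, 11.3-fold lower (10.3 to 12.4). The oestrogen sulfotransferase gene Sult1e1 was at 1439 and 274 CPM, 5.25-fold lower. Gsta3, Fam150b, Nmb and Inmt were 5.87-fold, 5.59-fold, 5.06-fold and 4.57-fold lower. The copper-binding ferroxidase gene Cp was 4.49-fold lower, the glutathione transferase gene Gstm1 3.80-fold lower and the opioid precursor gene Penk 3.76-fold lower.

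Of 28 collagen and crosslinking genes, 16 were higher, 8 were lower and 4 had intervals that held 1. Postn (ENSMUSG00000027750, chromosome 3, 54361109 to 54391037), which encodes a matrix protein of remodelling tissue, was at 202 and 567 CPM, 2.81-fold higher. Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042) was at 786 and 1906 CPM, 2.43-fold higher, and Col3a1 at 2976 and 5647 CPM. Col14a1 was lower, at 372 and 214 CPM. The list median was 0.09 log2, at percentile 99.3, and 0.25 after subtraction of free RNA. It was 0.48 among the 160 NCD and 66 HFD cells without markers of other classes.

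Of 17 genes of Dpp4 progenitors, the least committed cells of the lineage, 13 were lower in the HFD library and 4 higher. Dpp4 itself (ENSMUSG00000035000, chromosome 2, 62330073 to 62412231) was at 57.5 and 26.8 CPM, Anxa3 at 429 and 156 CPM, and Dact2 was 3.44-fold lower. The list median was −0.80 log2, below all 10000 random lists, and −0.64 after subtraction. Of 20 genes of committed preadipocytes, 13 were higher and 5 lower, with a median of 0.32, above all 10000 random lists, and 0.41 after subtraction. Among them Mgp was at 1211 and 4268 CPM, Clec11a was higher by 1.48 log2, and Gdf10 was 2.85-fold lower.

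Of 21 chemokine and acute phase genes, 13 were higher and 7 lower in the HFD library, with a median of 0.74 log2, above all 10000 random lists. Ccl5 was at 9.02 and 125 CPM, and the eosinophil attractant gene Ccl11 was lower, at 1941 and 615 CPM. After subtraction the median was −0.09, and Cxcl2 went from 3.09 to −0.02 log2, while in clusters with little free RNA the median was 0.72. Of 16 triglyceride synthesis and adipogenesis genes, 7 were higher and 6 lower, with a median of −0.00, at percentile 96.2, and −0.19 after subtraction. The fatty acid transporter gene Cd36 was at 25.5 and 247 CPM (3.28 log2, and 2.49 after subtraction) and Lpl at 799 and 1497 CPM. The fatty acid binding protein gene Fabp5 went from 1.38 to −0.77 log2 on subtraction.

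Cholesterol synthesis and uptake genes were lower for 13 of 15 members, with a median of −1.30 log2, below all 10000 random lists. Fdps, an enzyme gene of the pathway, was at 68.6 and 29.9 CPM, and its feedback inhibitor gene Insig1 was higher, at 48.5 and 113 CPM. This median was 0.18 among the 160 NCD and 66 HFD cells without markers of other classes. Unfolded protein response genes were lower for 18 of 20 (median −0.63), with Atf5, Sdf2l1 and Creld2 at −1.18, −1.15 and −1.05. All 12 mitochondrially encoded genes were higher (median 0.72), with mt-Cytb at 2300 and 4801 CPM. Complement genes were higher for 12 of 16 (median 1.02). All 7 MHC class II genes were higher (median 2.69), with Cd74 at 242 and 2131 CPM beside the macrophage markers. The median was 1.77 in clusters with little free RNA and 5.69 after subtraction. Of the 1987 HFD progenitors in such clusters, 1011 lay in a cluster with macrophage markers at 14.1% of the library level. The cluster of 374 cells had them at 20.5% and that of 286 cells at 5.01%. In NCD progenitors they were at 2.78%, so the 1.77 may still hold free RNA. Subtraction raised the median above 2.69, so the 5.69 is not read as a larger difference.

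After thinning to 2000 UMIs, which left out 172 NCD and 1488 HFD progenitors, Dpp4 had a UMI in 9.61% of NCD cells (8.58 to 10.7) and 4.13% of HFD cells (3.16 to 5.29). Unthinned, these shares were 18.6% and 5.42%, and in macrophages, as background, 0.166% and 1.19%. Pi16 was seen in 37.2% and 51.6% (unthinned 45.0% and 53.7%, background 2.93% and 18.9%). F3 was seen in 31.0% and 30.2% (unthinned 48.4% and 34.7%, background 0.829% and 7.96%). Col15a1 was seen in 35.3% and 44.0% (background 0.884% and 10.8%), but in 53.4% and 45.5% without thinning. Pparg was seen in 2.28% and 2.52% (unthinned 5.31% and 3.02%, macrophages 1.38% and 5.02%) and Mki67 in 0.165% and 0.700% (unthinned 0.219% and 0.549%, macrophages 0.940% and 2.47%). Icam1 was seen in 6.57% and 12.5% (unthinned 13.03% and 14.5%, macrophages 13.9% and 9.24%) and Ccl2 in 19.1% and 15.4% (unthinned 26.8% and 16.2%, macrophages 59.4% and 18.5%). Macrophages also transcribe these 4 genes, with Ccl2 at 916 CPM and Icam1 at 88.6 CPM in the NCD library, so their shares are no background. NCD progenitors lay mainly in cluster 9 (36.4%), cluster 8 (28.2%) and cluster 10 (21.6%), and HFD progenitors in cluster 3 (63.1%), so no cluster held most of both. The TMM and median of ratios factors of progenitors were −0.13 and −0.14 log2, so log2 ratios scaled by them lay higher by these amounts.

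**Figure D2:**
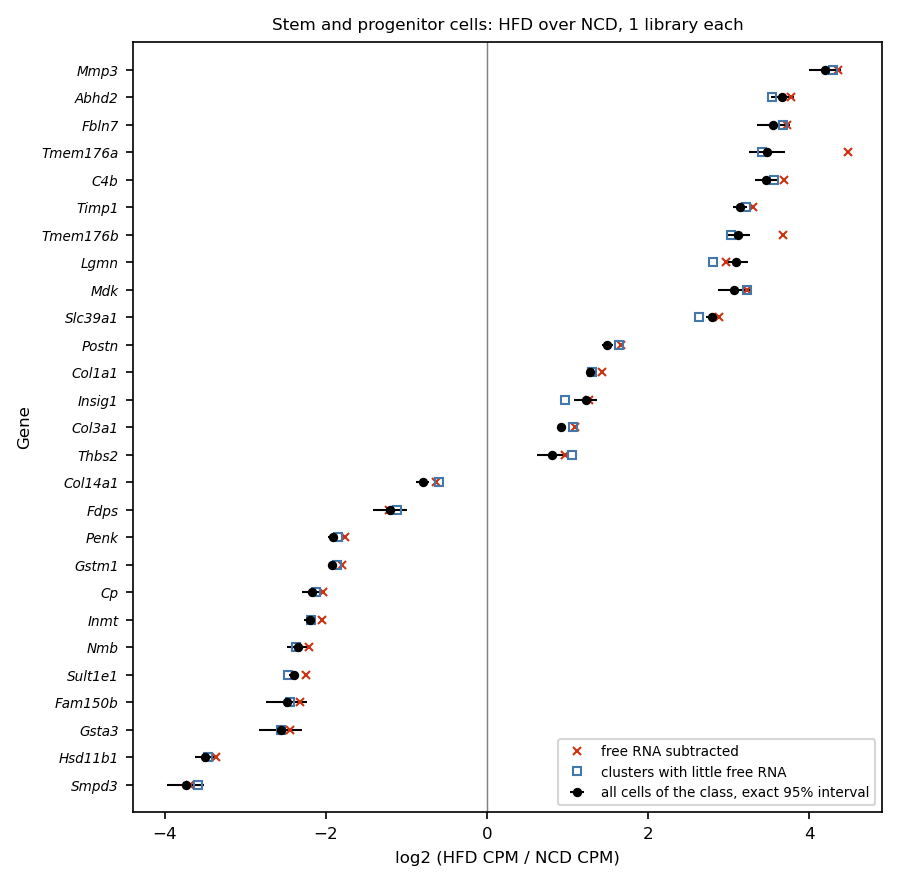
Log2 ratio of HFD CPM over NCD CPM of named genes in adipose stem and progenitor cells, for all cells with exact 95% intervals, after subtraction of free RNA, and in clusters with little free RNA. C4b lies at 3.47 and Smpd3 at −3.73, and the 3 settings lie close together for most genes.

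The fourth comparison concerned endothelial cells (338 NCD and 223 HFD cells, all in cluster 7). Within it 142 HFD and 13 NCD cells lay in cluster 7.3, while clusters 7.0, 7.1 and 7.2 held 118, 126 and 71 NCD cells and 16, 36 and 9 HFD cells, so the values compare different clusters. Plvap (ENSMUSG00000034845, chromosome 8, 71497765 to 71511752), which encodes a diaphragm protein of permeable vessels, was at 62.8 CPM in the NCD library and 479 CPM in the HFD library, 7.63-fold (5.93 to 9.90). Dll4, a Notch ligand gene of sprouting vessels, was at 106 and 18.7 CPM, 5.65-fold lower (2.98 to 12.0). Timp4 (ENSMUSG00000030317, chromosome 6, 115241892 to 115252205) was at 1207 and 204 CPM, 5.92-fold lower (4.87 to 7.25), and Art3, Tmem182 and Fam101b were 7.84-fold, 4.72-fold and 3.88-fold lower. In clusters with little free RNA the log2 ratio of Plvap was 3.26 and that of Dll4 was −2.50.

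Of 16 genes of endothelial lipid handling, 10 were lower, 1 was higher and 5 had intervals that held 1. Gpihbp1 (ENSMUSG00000022579, chromosome 15, 75596628 to 75599481), whose product anchors lipoprotein lipase to the vessel wall, was at 3850 and 1821 CPM, 2.11-fold lower (1.97 to 2.27). The transcription factor gene Tcf15 and the growth factor receptor gene Kdr were 2.44-fold and 2.24-fold lower, and Rbp7 was 2.16-fold lower. The list median was −0.73 log2, below all 10000 random lists. It was −0.12 in clusters with little free RNA (267 NCD and 72 HFD cells) and 0.49 after subtraction, which removed 62.0% of the HFD profile. Subtraction took out too much here: the ferritin gene Ftl1 went from 7937 to 0 CPM in HFD cells and stood at 3755 CPM in clusters with little free RNA. Subtracted endothelial values therefore carry little weight.

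Angiogenic tip genes were lower for 10 of 17 members (median −1.03 log2, −0.50 in clusters with little free RNA and 0.23 after subtraction), with Igfbp3 at −2.36 and Apln at −1.78. Activation and adhesion genes were higher for 8 of 19 and lower for 5 (median 0.46), with the leucine-rich glycoprotein gene Lrg1 at 1.67, Edn1 at 1.93 and Vcam1 at 1.32. Interferon response genes were lower for 13 of 29 and higher for 1 (median −0.70, −0.50 in clusters with little free RNA and 0.03 after subtraction), with Iigp1 at −1.36 and Xaf1 at −1.29. Collagen genes were higher for 23 of 27 (median 2.57, and 0.78 in clusters with little free RNA). Of the genes ranked highest, Timp1, Col1a1, Lum, Mgp, Cpxm1, Col3a1, Mfap5, Mmp2, Ifi205 and Pam are also transcribed by progenitors, and Col1a1 went from 5.55 to 2.44 log2 in those clusters. Of those ranked lowest, the macrophage genes Retnla and Mgl2 were 12.1-fold and 16.3-fold lower, and Lyve1 had 231 NCD and 3 HFD UMIs, 31.5-fold lower (10.7 to 154). Cluster 7.2, with 71 NCD and 9 HFD cells, had macrophage markers at 180% and 175% of their library level. The adipocyte genes Car3 and Cfd were also lower, and Cfd had 403 UMIs in NCD and 0 UMIs in HFD endothelial cells, at least 55.0-fold lower.

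The fifth comparison concerned T cells (138 NCD and 233 HFD cells, mainly in cluster 13, with 69.6% and 96.6% of them). Within it clusters 13.1, 13.2 and 13.3 held 55, 7 and 34 NCD cells and 6, 145 and 74 HFD cells, and cluster 6.0 held 42 and 8, so the values compare different clusters. Cd8a (ENSMUSG00000053977, chromosome 6, 71373427 to 71379173), which encodes a coreceptor of cytotoxic T cells, had a UMI in 7.81% of thinned NCD cells (10 of 128, 3.81 to 13.9) and 18.0% of thinned HFD cells (20 of 111, 11.4 to 26.5). Its shares were 13.8% and 21.5% unthinned and 0.0330% and 0.280% in progenitors, and 10 NCD and 122 HFD cells were left out. Median depth was 3362.5 and 1946 UMIs. Cytotoxic effector genes were higher for 11 of 16 members (median 0.85 log2), and the granule gene Nkg7 was at 464 and 929 CPM. The protease gene Gzma had 0 UMIs in NCD and 35 UMIs in HFD T cells, at least 14.1-fold higher. Klrg1, also a leading gene of type 2 innate lymphoid clusters 6.1 and 6.3, was 5.38-fold lower.

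Naive T cell genes were higher for 5 of 12 (median 0.64), with Dapl1 (ENSMUSG00000026989, chromosome 2, 59484653 to 59505020) at 50.4 and 192 CPM, 3.81-fold (2.57 to 5.78), and Lef1 at 1.27 log2. Regulatory T cell genes were lower for 5 of 13 and higher for 1 (median −0.62, and −1.41 in clusters with little free RNA), with the interleukin 33 receptor gene Il1rl1 at −3.37 and Areg at −1.61. Both genes also mark type 2 innate lymphoid cells, which lay in cluster 6 with 30.4% of NCD and 3.43% of HFD T cells. Of 18 activation and exhaustion genes, 4 were higher, 3 were lower and 11 had intervals that held 1, with a median of 0.25, at percentile 96.8, and 0.82 after subtraction. The exhaustion regulator gene Tox was at 37.0 and 86.0 CPM and the memory marker gene Cd44 at 271 and 87.7 CPM. Cell cycle genes were higher for 11 of 23 (median 0.94), with Nusap1 at 2.24 and Ube2c at 1.80.

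Of the genes ranked highest in T cells, Pam, Mgp and Lum are stromal and Trem2 is a macrophage gene (3 NCD and 132 HFD UMIs). Of those ranked lowest, Retnla, Lyz1 and Itgam (ENSMUSG00000030786) are myeloid genes, and Ltb4r1 was among the 10 leading genes of each cluster within cluster 6. Leaving out the T cell cluster with myeloid genes, a setting chosen after seeing the data, turned Lyz1 from −5.34 to 1.34 log2. Of the single-gene values in T cells, 9 moved beyond their interval with the same sign, 2 reversed and 6 stayed. That cluster, 13.1, had medians of 6458 UMIs in NCD and 4767 UMIs in HFD cells, so it weighs heavily in the NCD sums. It counted as a cluster with little free RNA. Cd4 was seen in 4.69% and 2.70% of thinned T cells (unthinned 8.70% and 3.004%), Pdcd1 in 8.59% and 5.41% (unthinned 13.8% and 9.01%) and Gzmk in 3.13% and 6.31% (unthinned 5.80% and 9.01%). Their intervals overlapped between the libraries, and no thinned progenitor share for these genes exceeded 0.140%. Foxp3 was seen in 0 of 128 and 0 of 111 thinned cells, and in 1.45% and 0.858% of unthinned cells. A floor of 3 cells allows shares of thinned cells with a UMI of up to 2.34% and 2.70%, which does not limit the cells that express the gene.

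**Figure D3:**
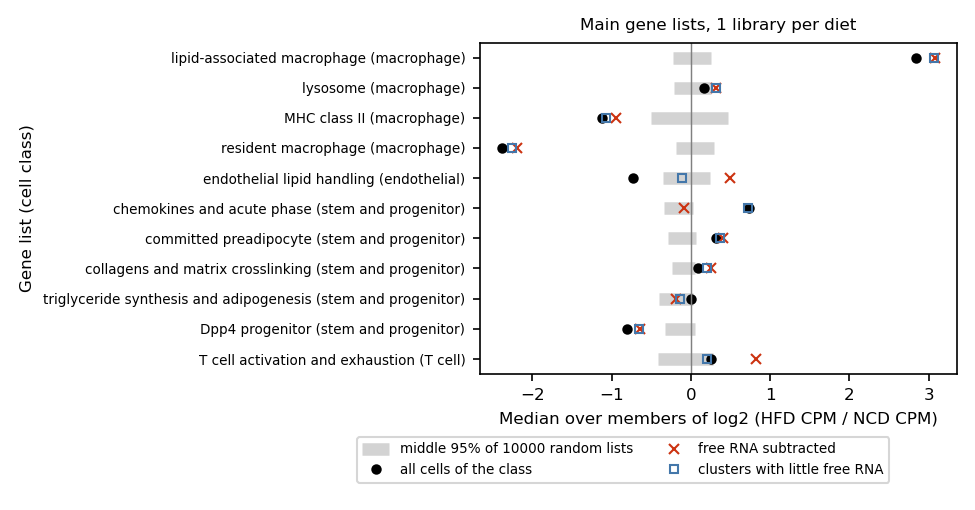
Median over members of the log2 ratio of HFD CPM over NCD CPM for the 11 main gene lists, in all cells of the class, after subtraction of free RNA, and in clusters with little free RNA. Grey bars are the middle 95% of 10000 random lists, and the lipid-associated (2.85) and resident (−2.39) macrophage lists lie farthest from them.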

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

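The settings that subtracted free RNA, kept only clusters with little free RNA, left out the T cell cluster with myeloid genes, or counted unnamed clusters as immune were chosen after the results were seen, and the other settings were planned. No paired analysis was possible because each library came from a different diet with no link between animals. Of the 11 main list medians, all kept their value within its interval under TMM, the median of ratios, totals without mitochondrial and ribosomal genes, the mean of CPM per cell, both member thresholds, kept doublets, marker scores and clusters with little free RNA. The interval of a list median covers the spread between list members and not counting error. It is wide, so a median could shift by much and still count as kept. The endothelial lipid handling median did so in clusters with little free RNA. For every value given in this part the cause was not tested. Values are log2 ratios unless another unit is given, and a value after "from" is the one with the main settings.

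The stricter cell filter gave shares of −0.11 for T cells, 0.0921 for progenitors, −1.44 for dendritic cells, 0.0095 for macrophages, 0.0312 for monocytes and 3.12 for mast cells or basophils. Classing each cell by its own marker score gave shares of 1.41 for T cells, −0.21 for progenitors, −0.38 for macrophages, −0.41 for monocytes, −1.23 for type 2 innate lymphoid cells and 1.38 for plasma cells. It also gave −0.28 (from 0.21) for the antioxidant list in mesothelial cells and −0.57 (from 0.86) for Tnfrsf4 in T cells. Keeping called doublets gave shares of 0.21 for progenitors, −0.97 for dendritic cells and 0.091 for macrophages. Thinning cells before clustering gave −0.85 for endothelial cells and 0.12 for macrophages. Resolution 0.5 gave 0.50 for B cells and −1.32 for dendritic cells, and resolution 2 gave −1.51 for dendritic cells, 0.0446 for macrophages and −0.30 for monocytes. No cell filter gave 0.44 for B cells. Counting unnamed clusters with immune scores as immune cells other than macrophages gave 0.25 for macrophages among immune cells.

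Leaving out cells with markers of other classes gave medians in progenitors of 0.18 for cholesterol synthesis and 0.48 for collagens. The oxidative phosphorylation list in progenitors, −0.08 as reported, came to 0.059 under TMM and 0.0638 under the median of ratios. The difference between the HFD and NCD percentages of progenitors with a Col15a1 UMI was −7.91 without thinning and 8.71 with it.

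Clusters with little free RNA gave shares of 0.35 for T cells, 0.24 for progenitors, −1.50 for dendritic cells, −0.97 for endothelial cells, 0.14 for macrophages, −1.51 for mesothelial cells, −0.15 for monocytes and 0.78 for plasma cells, and −0.0851 for Tnfrsf4 in T cells. This setting kept 6892 NCD and 3633 HFD cells and left out HFD cells unequally between classes. These shares therefore depend on the filter itself and do not measure frequency. Leaving out the T cell cluster with myeloid genes gave a T cell share of 1.59, and values of 1.34 for Lyz1 and 0.34 (from −3.51) for Batf3.

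Subtraction of free RNA gave medians of −0.39 (from 0.25) for the antioxidant list and −0.0353 (from 0.63) for the fatty acid oxidation list in B cells, and −0.65 (from 1.202) and −0.049 (from 0.49) for the lipid-associated list in dendritic cells and monocytes. In endothelial cells it gave medians of 0.21 (from −0.35) for MHC class I presentation, 0.49 (from −0.73) for lipid handling and 0.0325 (from −0.70) for interferon response. There it also gave −0.99 (from 4.90) for Lum, −1.18 (from 4.31) for Col3a1, 0.0108 (from −1.29) for Tcf15, 0.12 (from −1.16) for Kdr, 0.18 (from −1.11) for Rbp7, 0.21 (from −1.08) for Gpihbp1 and −6.16 (from 1.08) for Lpl. It gave −1.30 (from 3.30) for Ctsl and −1.69 (from 2.32) for Serpinb6a in dendritic cells, −0.77 (from 1.38) for Fabp5 and −0.019 (from 3.09) for Cxcl2 in progenitors, and 0.0368 (from −0.66) for Icos in T cells.

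Of the 163 single-gene values, 100 moved beyond their interval with the same sign when free RNA was subtracted, 12 reversed and 51 stayed within it. In clusters with little free RNA 99 moved, 1 reversed and 63 stayed. With doublets kept, 71 moved with the same sign and 92 stayed, and with marker scores 56 moved, 1 reversed and 106 stayed. Of the 32 shares of cells with a UMI, 13 moved with the same sign and 19 stayed when cells were thinned to 1000 UMIs.

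The mast cell or basophil share was at least 31.7-fold higher with thinned cells, where 0 NCD and 86 HFD cells were found. It had no value in clusters with little free RNA, since all 78 HFD cells lay in a cluster with much of it. The filter on markers of other classes was run only in progenitors. Under the stricter filter, lists and genes were not run for B, T, dendritic, mesothelial and monocyte classes, which had fewer than 50 cells in a library. Median depth in the HFD library limits the shares of cells with a UMI, since 3141 of its kept cells held under 2000 UMIs, against 608 in the NCD library.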

Other observations

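Of the tests below, the one for the innate lymphoid markers of the whole library was set before its result was seen, and the others after. An earlier test of free mast cell RNA was dropped, since it used barcodes classed by the same markers. In dendritic cells (365 NCD and 222 HFD cells) the chemokine gene Ccl17, which attracts T cells, was at 976 CPM in the NCD library and 29.0 CPM in the HFD library, 33.7-fold lower (21.97 to 54.5). The lectin genes Mgl2 and Cd209a, which mark type 2 conventional dendritic cells, were 12.3-fold and 4.89-fold lower. Fcrls, Dok2 and Gda were 16.6-fold, 8.45-fold and 5.61-fold lower, and Pdlim1, Ear2, Cd209d and Fam46a were lower by 5.34-fold, 4.87-fold, 4.71-fold and 4.53-fold. Cxcr4, a homing receptor gene, was 5.54-fold higher and Cd63 5.85-fold higher, while Pam, Mgp and Nfia moved with the stromal markers. In the HFD library 154 of the 222 cells lay in clusters with much free RNA, and the lipid-associated macrophage list had a median of 1.202 log2, 0.55 in clusters with little free RNA and −0.65 after subtraction. Cell cycle genes were lower for 14 of 23 members (median −0.72 log2, and −0.17 in clusters with little free RNA), with Birc5 at −1.32, and Mki67 had a UMI in 6.80% of NCD and 5.04% of HFD cells thinned to 2000 UMIs (unthinned 19.5% and 5.41%, progenitors 0.165% and 0.700%). Dendritic cells of the NCD library lay mainly in cluster 2 (54.2%) and those of the HFD library in cluster 14 (70.7%), so these values compare different clusters. Ccl17, Cd209a, Cd209d and Mgl2 were among the 10 leading genes of cluster 2.2, with 138 NCD and 31 HFD cells. Xcr1, Irf8 and Wdfy4 were among those of cluster 14.0.

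In monocytes (183 and 87 cells) 8 of 21 lipid-associated genes were higher and none lower (median 0.49, and −0.05 after subtraction of free RNA), with Trem2 at 79.6 and 198 CPM and the stress cytokine gene Gdf15 10.6-fold higher. In B cells (64 and 180 cells) cell cycle genes were higher for 7 of 20 and lower for none (median 0.72), with Stmn1 at 66.2 and 167 CPM, and the costimulator gene Cd86 was at 110 and 54.1 CPM. All NCD B cells lay in cluster 17 and 53.9% of HFD B cells in cluster 22.2, which held no NCD cell and had stromal markers at 70.2% and macrophage markers at 75.1% of their library level, so these values compare different clusters. In mesothelial cells (54 and 52 cells), which line the fat pad, identity genes were lower for 15 of 17 (median −1.45, and −0.90 after subtraction), with Msln at 1116 and 305 CPM and Krt7 at 361 and 80.0 CPM. Macrophage markers in these cells were at 2.29% of their library level in the NCD library and 33.7% in the HFD library, where 42 of the 52 cells lay in a cluster with much free RNA. Unfolded protein response genes were lower for 15 of 21 (median −1.17), with Hspa5 at 2581 and 669 CPM. The interferon-induced gene Isg15 was at 305 and 29.1 CPM. The acute phase gene Saa3 had 1 UMI in NCD and 35 UMIs in HFD mesothelial cells, and Cxcl1 was 19.1-fold higher.

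Stromal transcripts in HFD immune cells go in part with free RNA in the droplets. Within each of 8 immune classes the ratios of the 15 stromal markers to their library level had a narrow interquartile range, with ends at most 1.35-fold apart. That range leaves out the outer markers. In HFD natural killer cells Dcn was at 427 CPM against 5980 in the library, and Col3a1 at 374 against 2879, which are unlike fractions. The median ratio differed between classes, from 8.06% in monocytes to 104% in mast cells or basophils, and between macrophage clusters, from 6.16% to 112%. Free RNA with the library profile could at most reach the library level, so it does not by itself give the 104% and 112%. Expression of these genes by the immune cells under the diet would need most markers at about the same fraction of their library level. The same 1.35 counts against it as the whole cause, for the markers within the interquartile range only. Pairs of cells in 1 droplet would carry more UMIs. HFD macrophages in the highest 25% by stromal share had a median of 1901 UMIs and those in the lowest 25% had 4154.5, a ratio of 0.458. This cannot decide whether pairs contributed. The share was taken of the UMIs of each barcode, so barcodes with few UMIs can rank highest, and called doublets had been left out.

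Mast cells or basophils were more frequent in the HFD library. Classing by clusters does not account for the direction, since the 10 mast markers summed over the whole library were 43.6-fold higher (39.4 to 48.3). Only 23.3% of their NCD and 49.7% of their HFD UMIs lay in the class. The ratio of the shares did depend on classing, since marker score per cell gave 39 NCD and 382 HFD cells, a 10.8-fold higher share. Free mast cell RNA is not the whole cause either. At least 20 UMIs of these markers were held by 67 HFD barcodes of any class (51.9 to 85.1). A spread of the UMIs in proportion to those of each barcode would give 0.898. The 78 barcodes of the class also held stromal markers at 104% of the library level, so how many of them were whole cells stays open. A difference made by the diet and unequal recovery of cells by digestion or capture could each give this 43.6-fold difference, and neither was tested.

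Type 2 innate lymphoid cells were less frequent in the HFD library. Lower total UMIs at clustering do not account for this, since the log2 ratio was −3.93 with every cell thinned to 1000 UMIs beforehand. Thinning did not make free RNA equal, and the thinned clusters were named from unthinned counts. In T cells, for example, stromal markers were at 5.98% of the library level in NCD and 43.4% in HFD. Fewer transcripts of the cell itself in HFD barcodes therefore stay open as an explanation. Classing by clusters and a true difference in frequency cannot be told apart, since the 5 markers of this class summed over the whole library had a ratio of 0.428 (0.379 to 0.482), but only 41.3% of their NCD and 7.69% of their HFD UMIs lay in the class. A difference made by the diet and unequal recovery of cells could each give the value of −3.93, and neither was tested.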
